A study of Mus musculus with 10 samples.

How the data were processed

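RNA bound by the splicing regulator RBM20 was profiled by eCLIP, in which protein and RNA are crosslinked by ultraviolet light, immunoprecipitated, run on a gel, and the RNA from a window of the membrane is sequenced. Per the labels, tissue came from wild-type mice of 35 days, was crosslinked 3 times at 400 mJ/cm2, and the window ran from 55 to 145 kDa. Of 10 samples, 2 were heart eCLIP, 2 heart size-matched input, 3 olfactory bulb (OB) eCLIP and 3 OB size-matched input. The size-matched input is RNA cut from the same window without immunoprecipitation. Nothing in the labels states that replicates came from separate animals, so p-values over libraries measure only the spread between these samples, which may be technical.

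The submitters' processing notes name cutadapt 3.4, STAR 2.7.9, UMI-tools 1.1.1 and the mouse build mm10. Per the series' design text, reads were single-end, and of the paired-end OB replicate 3 only read 1 was used. CLIPper and featureCounts are named only in the names of the deposited tables, and their versions and settings are not given in the sources used here.

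Each tissue has a deposited peak table with 1 value set per peak, so eCLIP replicates could not be compared here, and which of them entered is not given in the sources used here. The authors give each peak a −log10 p-value, capped at 400, whose reference (input or local background) is not stated. They also give the −log10 local and global irreproducible discovery rate (IDR). The deposited score follows the global IDR, so that 540 corresponds to an IDR of 0.05. Gene symbol and feature of each peak are the authors' own. The peak tables held many clusters with a −log10 p of 0 and no fold over input. The set analysed was therefore every peak with a deposited p of 0.001 or below, the p part of the rule fixed before the data were examined. The fold part of that rule and the alternatives based on it could not be applied. A gene was called bound with at least 1 such peak. Coordinates are mm10, 1-based, with width taken as end minus start plus 1.

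The deposited input tables hold raw read counts per Ensembl gene for heart input replicates 1 and 2 and OB input replicates 1 and 2. They list genes with at least 10 reads in both libraries of a tissue, so the planned background of at least 1 read was the same set. OB input replicate 3 was not used here. Counts in listed genes were 5832118 and 12037136 in heart and 23448246 and 20035233 in OB. Libraries of a tissue differed beyond sampling noise, with a chi-square per degree of freedom of 15.5 in heart and 8.05 in OB. Gene span is the distance from gene start to end in these tables. No strand setting is given in the sources used here, so counts of overlapping and antisense genes cannot be told apart.

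Shares carry 95% exact Clopper-Pearson intervals, which cover counting error only, since peaks of a gene are not independent. Tissues were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within a family. For peak shares these tests treat peaks as independent. For list members they treat the tissues as separate sets, although most members are the same genes, so the pairing by gene was not used. Gene lists, 15 pathway lists and 11 marker lists holding 472 gene names of which 8 matched no symbol, were fixed before the data were examined and gave 52 tests in the tissues together. Each list was also set against 10000 random lists matched on the decile of input reads and the decile of gene span. Median spans were compared by a two-sided permutation test with 100000 resamples within deciles of input reads. Peak overlap required 1 bp on the same strand. Inputs were compared with edgeR's quasi-likelihood test (TMM scaling, filterByExpr), calling genes at an adjusted p of 0.05 or below and an absolute log2 fold of at least 1, with DESeq2 as an alternative. Fold changes are heart over OB over the 13538 genes listed in both tissues, so 749 genes listed only in heart and 4747 only in OB have none.

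The input test was checked on simulated counts for 13538 genes, where it recovered 96% of 100 genes changed by a log2 fold of 1.5 and 100% of those changed by 3, with 0 false calls. The simulation gave every gene the same dispersion and left all other genes equal between tissues, so false calls were unlikely by design. In the real inputs 10403 genes had an unadjusted p under 0.05 by edgeR's quasi-likelihood test. The check therefore does not cover false calls or scaling where most genes differ. The list test was checked with 200 random and 20 seeded lists per tissue. It called 0 random and 20 seeded lists in each. These lists were drawn regardless of input reads, so this check does not show how often the Fisher test calls lists of abundant genes. A check of the matched span test with a seeded effect of length gave ratios of 1.73 in heart and 1.85 in OB (permutation p = 0.0005 for each). With no effect of length the ratio was 0.848 (permutation p = 0.004) in heart, so that draw was repeated 40 times. Over 3 ways of choosing bound genes by reads the median ratio was then 0.981 to 1.05 in heart, with 5% to 12.5% of draws at a p of 0.05 or below. In OB, with binding in proportion to reads, the decile matching left a median ratio of 1.38 (1.21 to 1.72) with 100% of draws at a p of 0.05 or below, against 1.04 and 5% with 50 bins. By the square root or decile of reads the OB ratios with deciles were 0.95 to 1.23 and 0.801 to 1.16. For the real lists with such binding, decile matching put 17.2% of heart and 11% of OB lists above the upper limit of matched lists, and 50 bins 4.50% and 2.67%. Where 30% of members were added as bound, 50 bins found 35 of 40 lists in heart and 39 of 40 in OB. Matching on 50 bins was therefore added as an alternative for spans and lists.

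Named genes follow a rule fixed before the data were examined. Per tissue these are the 10 genes with the most peaks, the 10 genes with the smallest p (ties at the cap by the number of capped peaks, then peaks), up to 4 bound members per list by smallest p, and all bound literature targets. Of genes bound in both tissues, the 10 with the most peaks in both were taken. For the inputs, the 10 largest folds each way and up to 4 called members per list were taken, and Rbm20 always. Any other gene was chosen after its values were seen.

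Alternatives changed the peak threshold, the unit counted, the definition of bound, the background, the matching and, for the inputs, the scaling, filter, library left out and replicate block. The setting called without abundant non-coding RNA genes left out Rn45s, Malat1, Neat1, Mir6236 and all Snord and Scarna genes. Despite its name it also left out the protein-coding genes Lars2, Gphn, Cmss1, Cdk8, Camk1d, Hexb and Zfp791. A test of eCLIP against input, tests of the UCUU motif and of distance to splice sites, and leaving out eCLIP replicates were planned and not run, since counts per eCLIP library and a genome were not used here. Exonic length was likewise not used here. Gene synonyms came from a RefSeq table of GRCm38.p6. Software was Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9, bedtools 2.31.1, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.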

Results

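RBM20 binding was mapped by eCLIP in mouse heart, where RBM20 is known as a regulator of alternative splicing, and in the olfactory bulb (OB), the forebrain region that receives input from the nose. The groups were heart eCLIP (n = 2), OB eCLIP (n = 3) and their size-matched inputs (n = 2 and n = 3). The deposited peak tables listed 87386 peaks for heart and 209309 for OB, of which 7538 (8.63%) and 1434 (0.685%) had a p of 0.001 or below. These peaks had a median width of 100 bp (range 5 to 813) in heart and 90 bp (2 to 264) in OB. Input libraries held 5832118 and 12037136 reads in heart and 23448246 and 20035233 in OB. Peak values are the authors' and were given per tissue, so they carry no replicate error.

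In heart, RBM20 peaks lay in 737 genes, with the most in Ttn and Ryr2. Ttn, which encodes the giant sarcomeric spring protein titin, had 548 peaks. Ryr2, the calcium release channel of the sarcoplasmic reticulum, had 506, and the Rbm20 gene itself had 265. Pde4d, a cyclic AMP phosphodiesterase, had 139 peaks, the sodium-calcium exchanger gene Slc8a1 had 138, the actin-binding Palld 132, the nuclear receptor gene Rora 130, the formin gene Fhod3 122 and Sorbs1 120. Filip1l had 144 peaks and overlaps Cmss1 on the other strand. The 10 genes with the most peaks held 29.8% of all heart peaks, and 249 genes had a single peak.

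The Ttn gene (ENSMUSG00000051747) spans 278568 bp of the minus strand of chromosome 2, from 76703980 to 76982547. Its peaks lay between 76801405 and 76906706, a range of 105302 bp, with 335 annotated to introns and 213 to coding exons. Of them 499 were at the −log10 p cap of 400, against 579 capped peaks in the whole heart set. In Ryr2 (chromosome 13, 11553102 to 12106945, minus strand) 495 peaks were intronic and 5 peaks were at the cap. In Rbm20 (ENSMUSG00000043639, chromosome 19, 53677306 to 53867080, plus strand) 264 of 265 peaks were intronic, with a top −log10 p of 32.8, and peaks covered 13.3% of the gene span. Further genes at the cap were the nuclear non-coding RNA Malat1 (50 capped peaks), the Z-disc gene Ldb3 (9), the nuclear non-coding RNA Neat1 (8), Pde4b (2), and with 1 each the myosin heavy chain gene Myh6, the PI3-kinase subunit gene Pik3r1 and the antisense RNA Mhrt. Next was Lrrc58, with a top −log10 p of 78.1 and 27 of 30 peaks in its 3′ UTR.

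**Figure D1:**
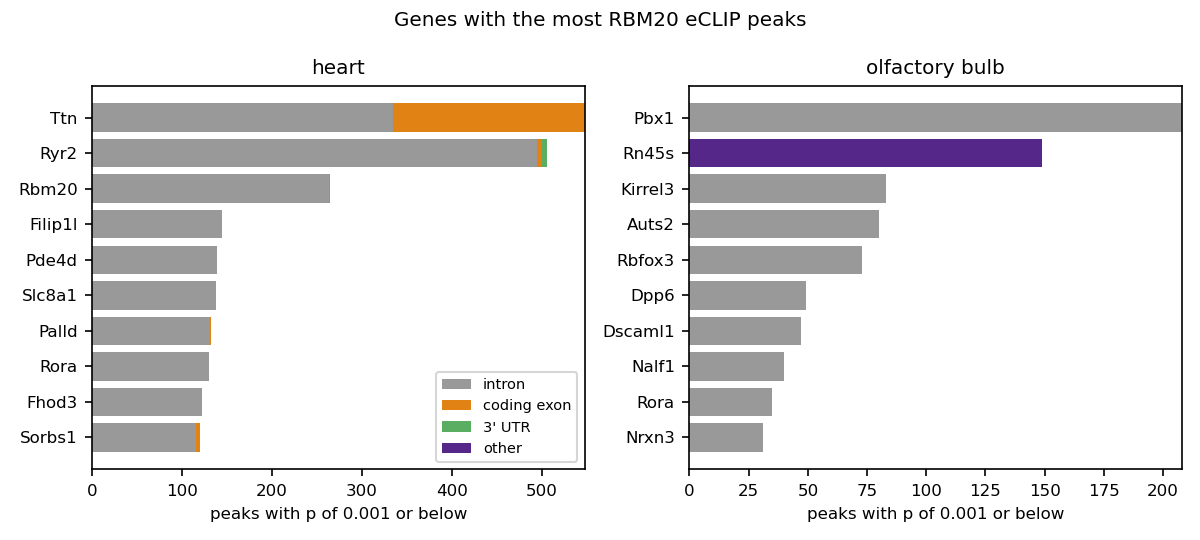
Number of peaks with a deposited p of 0.001 or below (horizontal axis) in the 10 genes with the most peaks in heart (left) and olfactory bulb (right), colored by the authors' annotation of each peak. Ttn leads in heart with 548 peaks, of which 213 lie in coding exons, and Pbx1 leads in olfactory bulb with 208 peaks, all intronic.

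Genes known from the literature as heart splicing targets of RBM20 were bound in heart far more often than other genes. Of 35 measured targets 18 were bound (51.4%, exact 95% interval 34.0 to 68.6), against 5.68% of all genes in the heart input (Fisher's exact test, adjusted p = 1.47e-12). Besides Ttn, Ryr2, Fhod3 and Sorbs1 they were Cacna1c, the L-type calcium channel gene, with 109 peaks, Obscn with 79, Ldb3 with 59, Mlip with 54, Myom1 with 35, Tnnt2 with 31, Tpm1 with 30, Nexn with 15, Camk2d with 14, Lmo7 with 12, Lrrfip1 and Pdlim5 with 10 each, Zfp451 with 8 and Trdn with 1. In Camk2d 6 peaks were intronic and 6 in the 3′ UTR, and in Zfp451 all 8 were in the 3′ UTR.

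Sarcomere and Z-disc genes were bound in 26 of 36 cases (72.2%, adjusted p = 2.07e-23), among them Tnnt2 with a top −log10 p of 71.5. Calcium handling genes were bound in 13 of 18 cases (72.2%, adjusted p = 4.96e-12), including Casq2 with 62 peaks. All 10 cardiomyocyte markers were bound (adjusted p = 4.96e-12). These lists share members, Ttn and Ryr2 among them. Bound more often than other genes were also the lists of intercalated disc and costamere genes (8 of 20, adjusted p = 2.86e-05), with Ctnna3 at 102 peaks, Ank3 at 36 and Lmo7 at 12, and of cardiac ion channels (8 of 20, adjusted p = 2.86e-05), with Scn5a at 15 peaks and Kcnh2 at 4. Fatty acid oxidation and mitochondrial energy genes followed (10 of 20, adjusted p = 3.14e-07), with Ckmt2 at 13 peaks, Fabp3 at 9 and Ppargc1a at 4. Splicing regulators (7 of 27, adjusted p = 0.0021) included Msi2 with 22 peaks, Rbm24 with 19 and Celf2 with 14, and housekeeping genes (4 of 16, adjusted p = 0.0332) included Ubc with 9 and Actb with 3.

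Against random lists matched on deciles of input reads and span, only the literature targets, sarcomere, calcium handling and cardiomyocyte lists stood above chance in heart (adjusted permutation p = 0.0026 for each). Matched random lists were bound in 21.6%, 29.3%, 27.6% and 40.3% of members. For the other lists past the Fisher test this p was 0.101 for ion channels, 0.941 for the intercalated disc, 0.433 for fatty acid oxidation, 0.534 for splicing regulators and 0.447 for housekeeping genes. With 50 bins of reads only the sarcomere list stood above chance, with 41.6% of matched members bound (adjusted permutation p = 0.0104), and this p was 0.222 for the literature targets, calcium handling and cardiomyocyte lists. In 1 or more other peak sets the Fisher tests of the ion channel, fatty acid oxidation, splicing regulator and housekeeping lists also missed the threshold. Markers of endothelial cells, fibroblasts, smooth muscle cells and pericytes, macrophages, blood and every neuronal or glial type tested had 0 bound members in heart. Measured were 8 endothelial, 6 fibroblast and 7 smooth muscle and pericyte markers. Their lists matched on deciles were bound in 18.4%, 26.3% and 12.5% of members (unadjusted permutation p = 0.359, 0.265 and 0.717). The other lists of these markers held 1 to 8 measured members, with matched shares of 0% to 8.19%. These counts of 0 therefore cannot be told apart from chance and do not show binding restricted to cardiomyocytes. Postsynaptic genes were bound in 4 of 28 cases (adjusted p = 0.207), with Homer2 at 16 peaks, of which 15 lay in the 3′ UTR.

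**Figure D2:**
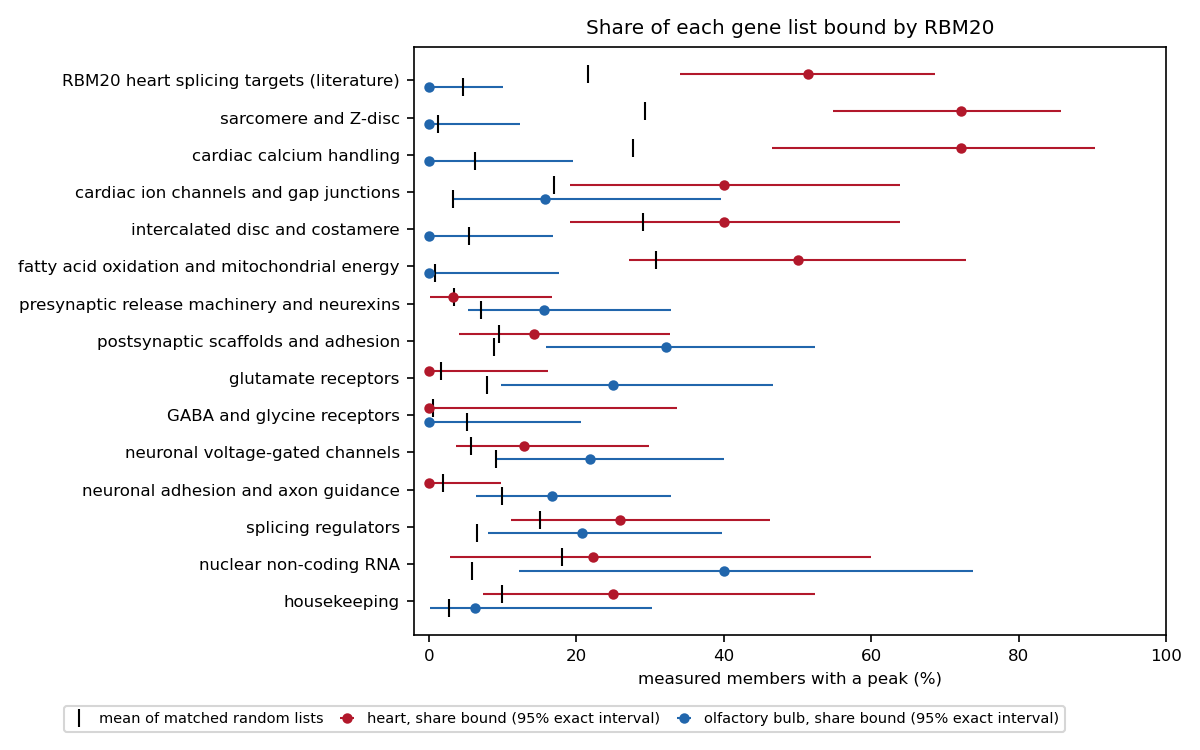
Share of measured members with at least 1 peak (horizontal axis, percent) for each of the 15 pathway lists in heart (red) and olfactory bulb (blue). Points are the share, lines its exact 95% interval, and black ticks the mean of random lists matched on input reads and gene span. Sarcomere and Z-disc genes were bound in 72.2% of cases in heart and 0% in olfactory bulb.

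In the OB, peaks lay in 194 genes. Outside ribosomal RNA those with the most peaks included genes for a transcription factor, adhesion proteins and a splicing factor. Pbx1, which encodes a homeodomain transcription factor, had 208 peaks. The adhesion gene Kirrel3 had 83 peaks, Auts2 80, the neuronal splicing factor gene Rbfox3 73, the potassium channel subunit gene Dpp6 49, Dscaml1 47, Nalf1 40, Rora 35 and the neurexin gene Nrxn3 31. All of these peaks were intronic. Rn45s, the precursor of ribosomal RNA, had 149 peaks. The 10 genes with the most peaks held 55.4% of OB peaks, and 98 genes had a single peak.

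The Pbx1 gene (ENSMUSG00000052534) covers chromosome 1 from 168119364 to 168432270 on the minus strand, and its OB peaks lay between 168262326 and 168427820, with a top −log10 p of 15.6. Kirrel3 (chromosome 9, 34485894 to 35036716, plus strand) had peaks from 34489922 to 34785642 and a top −log10 p of 8.90. The OB peaks at the cap lay elsewhere. Of 143 such peaks 114 were in Rn45s, 10 in Lars2, 5 in Snord3a, 3 in Gphn, 2 in Snord118 and 1 each in Cdk8, Zfp791 and Cmss1. Scarna2 and Peak1 followed with top −log10 p values of 36.12 and 36.10. In Lars2 the 10 peaks merged into 1 region of the 3′ UTR, and in Gphn the 3 peaks merged into 1 intronic region. Whether reads at the capped sites outside Rn45s come from sequence like that of ribosomal RNA was not tested, since no genome sequence was used here, so these peaks cannot be taken as binding to the genes named.

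**Figure D3:**
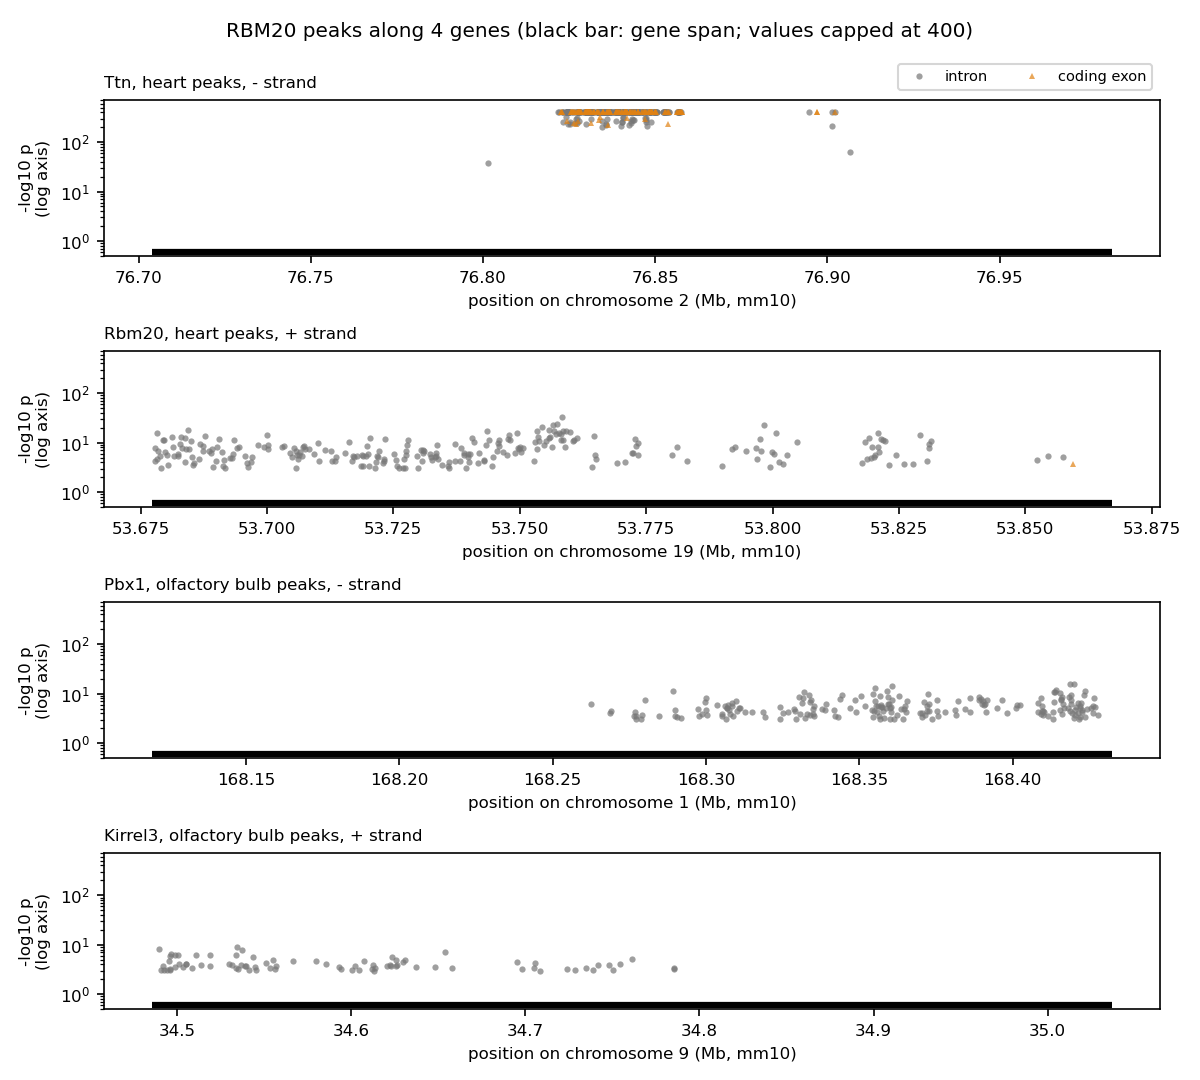
Position (horizontal axis, Mb, mm10) and −log10 p (vertical log axis, capped at 400) of every peak with a p of 0.001 or below in Ttn and Rbm20 in heart and Pbx1 and Kirrel3 in olfactory bulb. Gray circles are intronic peaks, orange triangles peaks in coding exons, and the black bar is the gene span. The 548 Ttn peaks fall within 105302 bp of a gene of 278568 bp.

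Synaptic and channel genes were bound in the OB more often than other genes, with 1.27% of all genes in the OB input bound. Postsynaptic scaffold and adhesion genes were bound in 9 of 28 cases (32.1%, Fisher's exact test, adjusted p = 4.17e-10), with Dlgap2 at 29 peaks, Dlgap1 at 6, Shank1 at 5 and Gphn at 3. Neuronal voltage-gated channels were bound in 7 of 32 cases (21.9%, adjusted p = 9.15e-07), with Dpp6 at 49 peaks, Kcnb2 at 11, Cacna1d at 7 and Kcnd3 at 1. Glutamate receptors were bound in 6 of 24 cases (25.0%, adjusted p = 2.81e-06), with Grik3 at 17 peaks, Grm4 at 11, Grin2a at 7 and Grin1 at 4, while 0 of 16 GABA and glycine receptors were bound. Splicing regulators (6 of 29, adjusted p = 8.37e-06) included Rbfox3, Celf4 with 20 peaks, Celf2 with 7 and Msi2 with 4.

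Nuclear non-coding RNAs were bound in 4 of 10 cases in the OB (adjusted p = 2.6e-05), namely Neat1 with 12 peaks, Meg3 with 11, Malat1 with 2 and Miat with 1. Adhesion and guidance genes (6 of 36, adjusted p = 2.61e-05) included Kirrel3 with 83 peaks, Ntm with 3, Negr1 with 3 and Cadm2 with 1. Presynaptic genes (5 of 32, adjusted p = 0.000178) included Nrxn3, and Ptprs, Ptprd and Syt1 with 1 peak each. The cardiac ion channel list (3 of 19, adjusted p = 0.00547) held Kcnd2, Kcnd3 and Kcnb1, which are also expressed in neurons. None of the 35 literature targets was bound in the OB. Of the cell type markers only Meis2, an OB inhibitory neuron marker, was bound, with 2 peaks. Rpl13a was the single bound housekeeping gene. Against random lists matched on deciles, the postsynaptic list, in which Gphn was counted as bound, and the nuclear non-coding RNA list stood above chance (adjusted permutation p = 0.00693 for each), and the other lists had values of 0.101 or more. With 50 bins of reads no OB list stood above chance (adjusted permutation p of 0.222 or more). The Fisher test of the nuclear non-coding RNA list missed the threshold at a global IDR of 0.05 (31.4 points above other genes, adjusted p = 0.0899) and over all listed peaks (2.59 points, adjusted p = 1). That of the presynaptic list missed it at a p at or below the median (5.55 points) and with at least 2 peaks per gene (2.51 points), that of the adhesion list at a p at or below the median (4.86 points), and that of the cardiac ion channel list in 4 settings (1.01 to 24.0 points).

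Rbm20 had 265 peaks at this threshold in heart and 0 in the OB, where 46 peaks were listed (29 at a global IDR of 0.05) with a top −log10 p of 2.06. Ryr2 had 282 listed OB peaks (86 at a global IDR of 0.05) with a top −log10 p of 2.93, and Ttn and Ldb3 had 0 listed OB peaks. Nrxn3 and Kirrel3 had 0 listed heart peaks. The share of members bound differed between tissues for the sarcomere list (72.2 percentage points higher in heart, Fisher's exact test, adjusted p = 1.15e-08), the literature targets (51.4 points, adjusted p = 5.09e-06), calcium handling (72.2 points, adjusted p = 6.43e-05), cardiomyocyte markers (100 points, adjusted p = 7.04e-05), fatty acid oxidation (50.0 points, adjusted p = 0.00227) and the intercalated disc (40.0 points, adjusted p = 0.0142). Glutamate receptors (0 of 21 bound in heart) and adhesion genes (0 of 36) missed the threshold for a difference (adjusted p = 0.081 for each). Of these 6 differences only that of the sarcomere list passed the threshold in every setting. No setting adjusted the differences for the level of each RNA in the tissues. At a global IDR of 0.05 the difference was 8.57 points for the literature targets, 30.4 for calcium handling and 25.0 for the intercalated disc, and over all listed peaks 20.0, 23.5 and 25.0 points, all short of the threshold (adjusted p from 0.0511 to 0.870). With the heart set reduced to 1434 peaks, 2 lists still differed, the literature targets and the sarcomere genes, while calcium handling (22.2 points), the intercalated disc (20.0), fatty acid oxidation (5 points) and cardiomyocyte markers (60.0) did not pass. Fatty acid oxidation also missed it at a p at or below the median (25.0 points). With the OB set extended to the heart number, 10 lists differed, among them adhesion genes with 21 of 36 bound in the OB, and the intercalated disc (25.0 points) was not among them.

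Peaks were mostly intronic in both tissues, and heart had the larger share in 3′ UTRs. Introns held 79.5% of heart peaks (exact 95% interval 78.6 to 80.4) and 84.3% of OB peaks (82.3 to 86.2, Fisher's exact test, adjusted p = 3.34e-05). The 3′ UTRs held 12.2% (11.4 to 12.9) and 0.976% (0.535 to 1.63, adjusted p = 1.86e-53), and coding exons 5.44% and 1.12% (adjusted p = 1.12e-15). The 5′ UTRs held 0.597% and 0.139% (adjusted p = 0.0313). Other exons, which include those of non-coding transcripts, held 2.19% and 13.2% (adjusted p = 2.21e-61), and 149 of the 189 such OB peaks were in Rn45s. In heart the 3′ UTR peaks lay in 227 genes, led by Lrrc58 with 27, Dnajb14 with 24, Tead1 with 21 and Pik3r1 with 18, of which Dnajb14 and Tead1 were chosen after their values were seen. In the OB 10 of the 14 were in Lars2, in the 1 capped region described above. Over all listed peaks the intron shares were 78.5% and 77.5%, which turns the direction of that difference. Coding exons then held 8.08% and 14.5% and other exons 0.601% and 0.365%, so these differences turned as well. The p-values above treat peaks as independent, which peaks of a gene are not. With 1 peak per gene and feature other exons held 0.89% and 4.46% (Fisher's exact test, adjusted p = 0.00249). The 5′ UTR difference then missed the threshold (adjusted p = 0.0564).

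Among 12218 genes in both inputs, 36 were bound in both tissues against 10.4 expected from independent sets (odds ratio 4.25, Fisher's exact test, p = 4.49e-11). Those with the most peaks in both were Rora (130 in heart and 35 in OB), Neat1 (51 and 12), Auts2 (9 and 80), Srrm2 (10 and 8), Prkce (9 and 8), Celf2 (14 and 7), Gse1 (5 and 20), Nav2 (5 and 26), Pbx1 (5 and 208) and Msi2 (22 and 4). Stratified by the decile of input reads, the Mantel-Haenszel odds ratio was 1.16 and no longer past the threshold. At the level of sites 39 heart peaks (0.517%) overlapped an OB peak, 14 of them in Neat1, 7 in Rora and 3 in Srrm2, and 2.72% of OB peaks overlapped a heart peak. The share depends on the threshold, with 2069 of 32583 heart peaks (6.35%) at a global IDR of 0.05 and 22871 of 87386 (26.2%) over all listed peaks. Within the shared genes 36 of 477 heart peaks overlapped, against a mean of 10.4 and a maximum of 23 over 1000 uniform placements of the OB peaks in the same gene spans. Of these 36 overlapping peaks, 14 were in Neat1. The placements did not follow where reads lie along a gene, which was not analysed here. The excess therefore does not separate shared binding from shared read coverage.

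The series concerns binding to long pre-mRNAs, so gene span was compared. Bound genes had a median span of 58608 bp in heart against 27712 bp in unbound genes (2.11 times), and 118090 bp in OB against 27011 bp (4.37 times). Genes over 100 kb made up 33.9% of bound and 16.6% of unbound genes in heart, and 51.6% and 16.2% in OB, where Auts2, Rora, Kirrel3 and Pbx1 are examples. Compared with genes matched on the decile of input reads, the ratio was 0.757 in heart (permutation p = 1e-05, the smallest that 100000 resamples can give) and 1.12 in OB (permutation p = 0.161). With 50 bins of reads the heart ratio was 0.708, 0.712 without abundant non-coding RNA genes and 0.668 with at least 2 peaks per gene (permutation p = 1e-04 for each). The OB ratio with 50 bins was 0.726 (permutation p = 0.0018), and 0.908 without abundant non-coding RNA genes (permutation p = 0.397). With deciles the latter was 1.38 and with at least 2 peaks per gene 1.63, while simulated binding with no effect of length gave 1.21 to 1.72 with deciles when in proportion to reads, 0.95 to 1.23 when to their square root and 0.801 to 1.16 when by decile. Whether these 2 values exceed what reads alone give therefore depends on how binding follows reads, which was not measured. Input reads correlated with span across genes (Spearman rho 0.45 in heart and 0.607 in OB). Across bound genes, which are not independent replicates, peak number correlated with span with a Spearman rho of 0.191 (Pearson r 0.21, 726 genes, permutation p = 1e-05) in heart and 0.286 (Pearson r 0.174, 190 genes, permutation p = 0.00015) in OB. Given input reads, the partial rho was -0.0535 and -0.101.

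**Figure D4:**
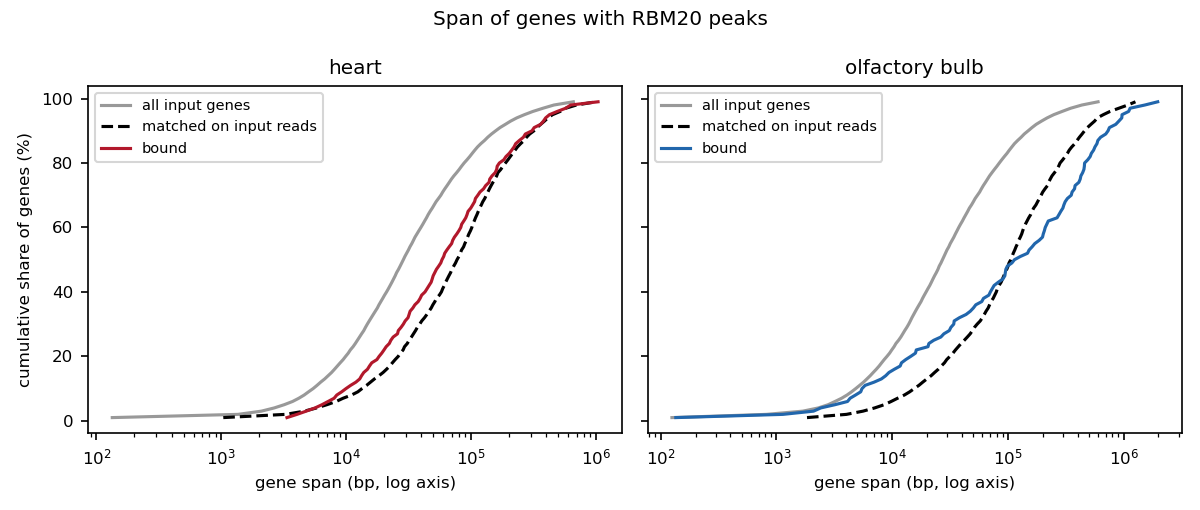
Cumulative share of genes (vertical axis, percent) by gene span (horizontal log axis, bp) in heart (left) and olfactory bulb (right) for all genes in the input (gray), genes with an RBM20 peak (colored) and genes weighted to match the bound genes by decile of input reads (dashed). The median of bound genes, 58608 bp in heart and 118090 bp in olfactory bulb, lies above that of unbound genes, and in heart it lies below the matched genes.

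The inputs show the RNA background of each tissue. Among genes listed in both inputs the largest log2 folds of heart over OB were 10.65 for the myoglobin gene Mb (SE 0.242), 10.36 for Pln, 10.25 for Hspb7, 10.18 for Actc1, 10.10 for Tnnt2, 9.84 for Myh6, 9.73 for Lpl, 9.38 for Myl2, 9.33 for Ttn and 9.21 for Myl3. The largest toward OB were -7.94 for Cdh10 (SE 0.193), -7.71 for the glutamate receptor gene Grm5, -7.63 for Galntl6, -7.57 for Brinp1, -7.54 for Mgat4c and Cdr1os, -7.51 for Cntn1, -7.49 for Dcx, -7.43 for Lrrtm4 and -7.41 for Epha5. Rbm20 RNA was at 1254 ± 71.7 CPM in heart (SD, n = 2) and 86.0 ± 3.61 in OB (SD, n = 2), a log2 fold of 3.87 (SE 0.156, edgeR adjusted p = 1.03e-11). Of 13538 genes listed in both tissues, 3338 were higher in heart and 2614 higher in OB by edgeR's quasi-likelihood test. A further 749 genes were listed only in heart and 4747 only in OB, and these have no fold and are outside the ranking and both counts, so the counts do not show which tissue had more genes higher. Examples chosen after their values were seen are Mybpc3, at 644 and 665 CPM in heart, and Neto1, at 273 and 303 CPM in OB.

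Of 28 sarcomere genes measured in both inputs 25 were higher in heart (25 also when adjusted over the list alone) with a median log2 fold of 7.34, and of 19 fatty acid oxidation genes 18 (18 adjusted over the list alone) with a median of 3.87. All 9 cardiomyocyte markers were higher in heart. All 21 glutamate receptors, 9 GABA and glycine receptors and 36 adhesion genes were higher in OB, with medians of -5.97, -6.52 and -5.86. Among the 35 literature targets 17 were higher in heart, such as Obscn (8.43), Ldb3 (7.75), Nexn (7.40) and Myom1 (7.28), and 5 higher in OB. Endothelial (7 of 8), fibroblast (5 of 5), smooth muscle and pericyte (6 of 6), macrophage (6 of 8) and blood markers (3 of 3) were also higher in heart, while astrocyte (5 of 7) and inhibitory neuron markers (4 of 4) were higher in OB. Upper-quartile scaling moved the median of all genes by 0.24 on the log2 scale, less than each list median given here, and called 3946 genes higher in heart and 2106 higher in OB. A single gene, ENSMUSG00000106106 (chromosome 17, 39846353 to 39848201), took 19.8% and 24.3% of the reads in heart and 5.91% and 5.78% in OB.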

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

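The test of the 3′ UTR share over all listed peaks, the matching of spans and lists on 50 bins, the peak sets by IDR, of all listed peaks, at equal number and without abundant non-coding RNA genes, and the density against the shortest quartile were chosen only after the results were seen. The share of list members bound differed between heart and OB, by Fisher's exact tests of the difference, for 6 lists. The heart share was higher by 51.4 percentage points for the literature targets of RBM20, by 72.2 for sarcomere and Z-disc genes, by 72.2 for calcium handling, by 40.0 for the intercalated disc, by 50.0 for fatty acid oxidation and by 100 for cardiomyocyte markers. At a global IDR of 0.05 the difference fell to 8.57 points for the literature targets, 30.4 for calcium handling and 25.0 for the intercalated disc, none past the threshold, nor were these 3 over all listed peaks (20.0, 23.5 and 25.0). Fatty acid oxidation (5 points) and cardiomyocyte markers (60.0) missed it with heart reduced to the OB number, so only the sarcomere difference held in all settings. No setting adjusted that difference for the level of each RNA, and 25 of 28 sarcomere genes in both inputs were higher in heart. In OB, lists matched on deciles of reads and span were bound in 1.26% of members. The 0 of 28 sarcomere genes bound there therefore cannot be told apart from low abundance. The annotation of peaks differed as well. Heart minus OB was -4.78 percentage points for introns, 11.2 for 3′ UTRs, 4.32 for coding exons, 0.458 for 5′ UTRs and -11.0 for other exons.

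For the gene lists, abundance and length of the members were weighed as a cause. With random lists matched on deciles of reads and span 5 of the 9 heart and 6 of the 8 OB lists past the Fisher test lay above the central 95%, most of them, which was set beforehand to argue against that cause (4 and 2 after adjustment), but with simulated binding in proportion to reads that matching put 17.2% of heart and 11% of OB lists above the central 95%, against 4.50% and 2.67% with 50 bins. With 50 bins it was 5 of 9 and 3 of 8. The sarcomere list was bound 30.7 points above its matched lists (adjusted permutation p = 0.0104), an excess that abundance and length as matched by 50 bins did not account for. Its matched share rose from 29.3% with deciles to 41.6% with 50 bins, so abundance differences left within bins cannot be excluded as a cause. Of the 8 other heart lists 4 lay above and of the 8 OB lists 3, none past the threshold after adjustment, so for these abundance and length cannot be told apart from a preference for the list. Rbm20 RNA was higher in heart (log2 fold 3.87), and RBM20 protein, which was not analysed here, may contribute.

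For the 3′ UTR share, a few genes with many peaks and the p threshold were weighed. With 1 peak per gene and feature heart still exceeded OB 10.2 times (Fisher's exact test, p = 1.01e-16), which argues against a few genes such as Lrrc58 or Dnajb14 as the cause. Over all listed peaks the ratio was 1.75, so the threshold alone does not create the difference, but the ratio was 12.4 at a p of 0.001 and its size stays open. A tissue difference in where RBM20 binds remains a hypothesis, since differing RNA composition was not tested.

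For the long span of bound genes, abundance and uniform peak density were weighed. Matching on input reads left a span ratio of 1.12 in OB, inside the range of 1.2 times set beforehand for abundance as the cause. In heart it was 0.757, and with 50 bins of reads, added after the result was seen, OB gave 0.726, both under that range. The OB ratios with deciles were 1.38 without abundant non-coding RNA genes and 1.63 with at least 2 peaks per gene. They lie within the 1.21 to 1.72 of simulated binding in proportion to reads. They lie above the 0.95 to 1.23 and 0.801 to 1.16 of binding by the square root or decile of reads. Because reads correlate with span the matching may remove part of an effect of length, although a seeded effect left 1.73 in heart and 1.85 in OB. In OB abundance and length therefore cannot be told apart here. In heart 0.757 with deciles and 0.708 with 50 bins lie below the lowest simulated ratios with no effect of length, 0.846 and 0.835. For which heart genes are bound, these values argue against a preference for long spans beyond input reads. Peaks per 10000 input reads over all heart input genes went the other way. By quartile of span, shortest first, they were 2.00, 5.15, 5.10 and 7.63. Whether length matters beyond input reads therefore stays open in heart as well. Peaks per 100 kb in the longest quartile of all input genes were 0.859 times those of the other quartiles in heart (bootstrap 95% interval 0.582 to 1.23) and 2.75 times in OB (1.50 to 4.75), and against the shortest quartile alone 0.512 (0.280 to 0.957) and 0.682 times (interval including 1). The outcome set beforehand against uniform density, more than 1.5 times in both tissues, was not met. In OB alone the first ratio argues against a uniform density, but these densities per 100 kb were not adjusted for reads. Per 10000 input reads, OB peaks over all input genes were 0.255, 0.138, 0.0973 and 0.390 from the shortest to the longest quartile. In heart the first ratio met the 1.5 times set beforehand for uniform density, and only the comparison added later left out 1. Uniform and falling density therefore cannot be told apart in heart, and no biological explanation of span was tested.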

How the results depend on the processing

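The peak set at an IDR of 0.05, all listed peaks, merged peaks, leaving out abundant non-coding RNA genes, equal peak numbers and matching on 50 bins were chosen after seeing the data. Of 180 main results under an alternative 109 stayed within their limits, and of 184 values of single lists 151 did, 31 missed the threshold and 2 reversed. Causes were not tested unless stated.

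At a p at or below the median of each set there were 3769 heart and 717 OB peaks in 362 and 108 genes, with 14 genes in both, 20 overlapping peaks, intron shares of 74.4% and 71.4% (ratio 1.04, reversed), a heart 3′ UTR share of 13.2%, an OB span ratio of 0.951 (reversed) and 5 OB lists. At a global IDR of 0.05 there were 32583 and 44991 peaks in 2804 and 4334 genes, 1416 genes in both, 2069 overlaps, intron shares of 86.6% and 92.9%, 3′ UTR shares of 8.79% and 1.92% and an OB span ratio of 0.98 (reversed). Over all listed peaks there were 7313 and 10226 genes, 87386 and 209309 peaks, 6223 genes in both, 22871 overlaps, intron shares of 78.5% and 77.5% (ratio 1.01, reversed), an OB 3′ UTR share of 6.70%, an OB span ratio of 0.871 (reversed) and 13 lists that differed between tissues.

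Merging peaks within 100 bp gave intron shares of 83.1% and 94.7%. Without abundant non-coding RNA genes these were 80.9% and 96.8%, with 24 overlaps and an OB span ratio of 1.38 with deciles, past the threshold, a value that simulated binding in proportion to reads also gave. With heart reduced to 1434 peaks there were 107 bound genes, 9 in both tissues, 20 overlaps, an intron share of 62.8%, a rank correlation of peak number and span of 0.141, past the threshold no longer, and 2 lists that differed. In that setting the heart share bound of cardiac ion channels and of housekeeping genes, minus that of other genes, was -0.814 points (reversed). With OB extended to the heart number 119 genes were bound in both and 10 lists differed. With at least 2 peaks per gene 21 genes were bound in both and the OB span ratio was 1.63 with deciles, past the threshold and also within that simulation. Within 100 bp 59 peaks were shared.

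Without matching the span ratio was 2.11 in heart (reversed) and 4.37 in OB, and with 50 bins it was 0.726 in OB, 0.908 without abundant non-coding RNA genes and 0.789 with at least 2 peaks per gene (all reversed). Given reads the correlation of peak number and span was -0.0535 in heart and -0.101 in OB (both reversed). The odds ratio of shared binding by decile of reads was 1.16 and no longer past the threshold. Counting 1 peak per gene and feature gave 59.1% and 86.6% in introns and 25.3% and 2.48% in 3′ UTRs. By base pairs the heart 3′ UTR share was 13.7% and the OB intron share 94.2%. Random lists matched on deciles left 4 heart and 2 OB lists, and on 50 bins of reads 1 and 0.

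For the inputs, leaving out each library gave 3243 to 3439 genes higher in heart and 2565 to 2720 higher in OB, and the lone sample is then assumed to vary like the other group. The replicate block gave 3349 and 2615, and same-numbered libraries did not deviate together (correlation -0.00257). With so few libraries per tissue this cannot show whether same-numbered samples came from the same animal. DESeq2 gave 3265 and 2593. Leaving out OB replicate 3, eCLIP replicates, fold thresholds, motif and splice site tests were not run, and reducing OB peaks to the heart number changes nothing, as OB has fewer. The smaller OB peak set limits what its lists can show, and heart inputs were the shallower.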

Other observations

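Members of the CaMKII family of calcium-dependent kinases, picked after their values were seen, were compared between heart and OB. Camk2d had 14 heart peaks and 0 OB peaks at a p of 0.001, and Camk2b had 19 OB peaks (top −log10 p 7.51) and 0 in heart, where 1 peak was listed. Camk2a and Camk2g had 0 in both tissues. The split rests on the threshold, since Camk2d had 69 listed OB peaks (9 at an IDR of 0.05) and Camk2a 79 (16 at an IDR of 0.05), and it was not tested. Heart 3′ UTR peaks were also frequent in Uhmk1 (17), Mylk4 (16), Nucks1 (16), Tnpo1 (16), Homer2 (15) and the Musashi gene Msi2 (15), while Msi2 had only intronic peaks in OB (4).

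A test written before its result asked whether intronic peaks of genes over 100 kb lie toward the 5′ end. The mean relative position per gene (0 at the 5′ end, 1 at the 3′ end) was compared with that of peaks of the same genes with a deposited p of 1. In OB it was 0.341 against 0.441 over 90 genes, a mean difference of -0.100 (SD 0.196, lower in 65 genes, sign-flip permutation p = 1e-04, the smallest that 10000 flips can give). In heart it was 0.459 against 0.425 over 121 genes, a difference of 0.0334 (permutation p = 0.171), so the hypothesis did not hold there. Whether the tissues differ was not tested. In OB a 5′ preference of called peaks, as in Pbx1 and Kirrel3, may exist, but coverage along pre-mRNA was not analysed here.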
